A study of Mus musculus with 8 samples.

How the data were processed

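RNA was measured in the part of the small intestine next to the stomach, 5 cm long, of male mice aged 6 months. In 4 mice Pdx1 exon 2, which encodes the DNA-binding homeodomain, was flanked by loxP sites and removed in the gut epithelium by Cre recombinase driven by a 12.4 kb piece of the mouse villin gene promoter. The other 4 mice were littermate controls. Per the labels' protocols the tissue was kept in RNAlater, total RNA was extracted with a column kit and treated with DNase, and biotin-labelled cRNA was made by in vitro transcription and hybridised to Affymetrix arrays. All mice ate a standard diet with 4.5% fat.

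The authors deposited a single table of log2 expression values, with a value for each probe set and array. Partek 6.4 is named in the submitters' processing notes, which give it no role. The background correction, summarisation and normalization behind the values are not given in the sources used here. The log2 scale was taken from the values, which ran from 2.55 to 14.83, with array medians between 5.23 and 5.28. Such similar medians mean that a shift of all transcripts together could not be seen. The table gave no detection calls, so dim probe sets carry an unknown share of background, and a change in a dim probe set can be understated. Scanner files were not analysed here. For arrays there is no read depth: the number of arrays limits the precision. Pearson's r between pairs of arrays, across probe sets, lay between 0.990 and 0.996, and no pair of arrays held the same values.

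The table had 45101 probe sets. Of these, 64 were array controls and were left out of the tests, which left 45037. Gene names came from GEO's platform annotation: 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Of the probe sets with 1 symbol, 34741 were matched by Entrez identifier to the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. They covered 18193 genes. Probe sets with several symbols or none were tested but not given a gene name. No coordinates are printed, since the files name no genome build.

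Groups and replicate numbers came from the labels. The comparison was knockout minus control, fitted for each probe set with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no filter, covariate or block. The test was two-sided, p-values were adjusted over the 45037 probe sets by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as changed. Values per group are means ± SD over 4 samples. The labels call the samples biological replicates. Single values per sample, such as a gene list score, were compared by a two-sided exact permutation test, whose smallest possible p with 4 against 4 samples is 0.0286. These p-values were not adjusted over the lists, so a list score that separates the groups is weak evidence by itself.

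Before the data were examined, 42 gene lists were fixed, covering functions of the small intestine and the cell types that whole tissue could hold. In the lists a gene was represented by its probe set with the highest mean over the 8 samples. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 lists, and again with a correlation estimated for each list. A list score is the mean, over members, of a sample's deviation from each gene's mean over the 8 samples. The rule for named genes was fixed at the same time. It took Pdx1 and Vil1, up to 12 changed genes in each direction by size of log2 change, and up to 4 changed members of each list. Where fewer than 5 genes passed in a direction, the 10 with the smallest p in that direction were named. Where no member of a list passed, up to 2 members with the smallest p could be named.

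The scripts were tested on simulated data with the spread of the real knockout and control arrays. Among 45037 probe sets, 50 were changed at each of 4 sizes. At a log2 change of 0.5 the test recovered 48.0% of them, at 1 it recovered 88.0%, at 1.5 it recovered 98.0% and at 2.5 all 50, with 12 false calls in total. More probe sets were called there than the 19 in the real data. The adjustment then lets larger p pass, so these shares may overstate the recovery in the real data. The list test, run over 18193 genes simulated independently of each other, called 0 lists with nothing changed. With 1 list shifted by 0.3 it called that list and 1 other.

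The alternatives fixed beforehand were a block on the replicate number, a repeated quantile normalization, median centring, a minimum on the mean, a floor at 5, a trended and robust prior, array weights, an ordinary linear model, other thresholds, an estimated correlation for the lists, the mean of a gene's probe sets, and each sample left out in turn. Fits without control 2 and knockout 3 and with an exocrine pancreas score as a covariate, and list scores without the changed members, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.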

Results

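Transcript levels were measured in the proximal small intestine of 4 mice that lacked Pdx1 in the gut epithelium and of 4 littermate controls. Pdx1 is a homeodomain transcription factor of the duodenum and pancreas. The study asked how the transcripts of the mature proximal small intestine differ when the epithelium lacks it. Each sample was whole tissue on a single array, so the values mix epithelium with muscle, nerve, immune cells and any attached tissue. Array medians were 5.25 ± 0.017 in the knockout and 5.26 ± 0.0090 in the control on the log2 scale (SD, n = 4 each), and the number of arrays limits the precision.

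Pdx1 transcripts were lower in every knockout sample than in any control sample. The brighter of its 2 probe sets read 5.93 ± 0.25 in the knockout and 8.52 ± 0.36 in the control (SD, n = 4 each), a log2 change of -2.59 with a standard error of 0.18 and an adjusted p of 4.16e-04 in limma. The dimmer probe set read 5.05 ± 0.11 against 6.90 ± 0.34, a change of -1.85 (adjusted p = 0.00107 in limma). The sources used here do not say whether either probe set reads the removed exon, so these values check the labels only as far as the transcript level follows the deletion. Vil1, which encodes the microvillus protein villin and whose promoter drives Cre, read 12.79 ± 0.059 in the knockout and 12.60 ± 0.092 in the control. Its change of 0.19 did not pass the test (adjusted p = 0.660 in limma).

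Beyond Pdx1, the knockout intestine had lower transcripts for the hormone Gip, the phosphatase Akp3, the enzyme Ugt2b38 and the calcium-binding protein S100g. Transporters of iron, calcium, manganese, sulfate and thiamine were lower too. Transcripts were higher for the metal-binding protein Mt1 and the actin Acta1. In all, 19 of 45037 probe sets changed, which stood for 12 genes and 1 probe set with no gene symbol. Of the 19, 17 were lower and 2 were higher in the knockout, and the probe sets with a symbol came from 10 lower genes and 2 higher ones. In all 19 the knockout and control values did not overlap. Over all probe sets 4.43% had such separated groups, against 2.86% by chance. The probe set with no symbol fell by 1.77. At an unadjusted p under 0.05 there were 3210 probe sets, 7.13% of those tested, 1578 higher and 1632 lower. In an ordinary linear model without limma's pooling of the variance 2 probe sets passed, and with values under 5 set to 5 there were 4. Of the 19 reported, 1 was among the former, a probe set of Mt1, and 2 were among the latter, from Mt1 and Atp2b1. The other changed genes, Pdx1, Gip and Akp3 included, passed in neither setting.

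**Figure D1:**
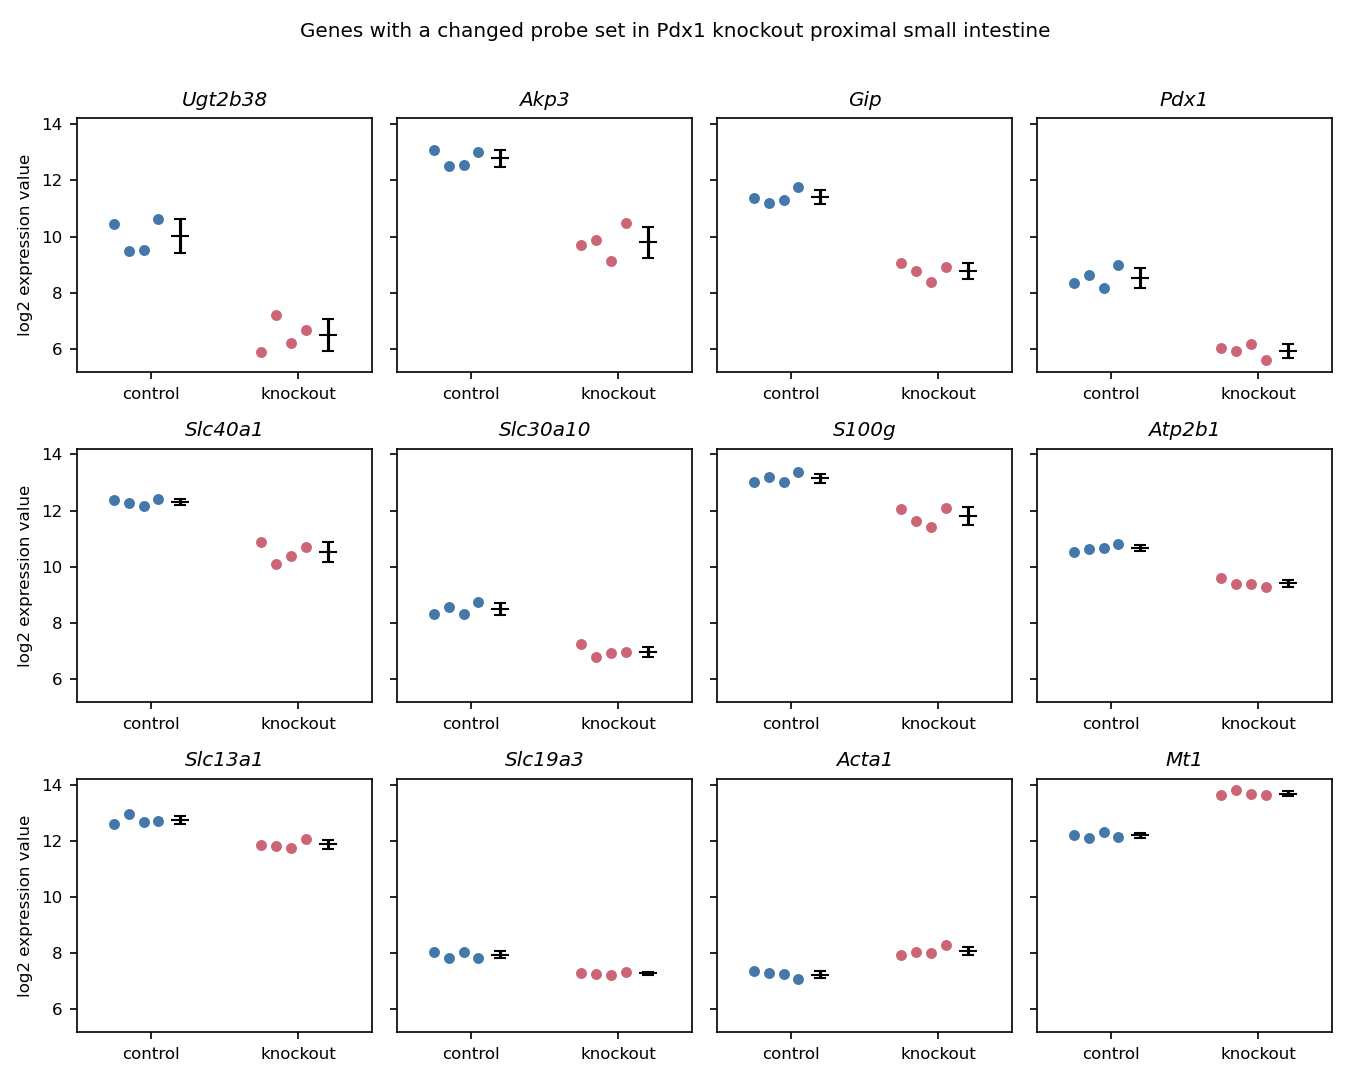
Log2 expression values of the 12 genes with a changed probe set, a panel per gene, with a point for each of the 4 control and 4 knockout samples and a bar for the mean ± SD; the probe set with the smallest p is drawn. In each panel the groups do not overlap, from Ugt2b38 with a change of -3.53 to Mt1 with a change of 1.48.

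The calcium absorption list was the fixed list with the most changed members, though 1 of them, Slc30a10, is not known as a calcium gene. Of 12 measured members of the calcium absorption list, 3 fell, 0 rose and 9 did not pass the test. S100g, the cytosolic calcium-binding protein calbindin-D9k, fell by 1.35, from 13.15 ± 0.16 in the control to 11.80 ± 0.32 in the knockout (SD, n = 4 each; adjusted p = 0.00950 in limma). Atp2b1, a calcium pump of the plasma membrane, fell by 1.25, 1.12 and 1.09 on its 3 changed probe sets. The probe set at -1.09 lost its call without control 1 (adjusted p = 0.0588), control 2 (0.136), control 3 (0.0658), knockout 2 (0.186), knockout 3 (0.0576) or knockout 4 (0.127), while the others kept theirs with any single sample left out. The same probe set also lost its call with an exocrine pancreas score as a covariate, a fit chosen after seeing the data (0.118). Its change there was still -1.08. Without control 2 and knockout 3 together it lost its call too (0.182). Slc30a10 fell by 1.52 and 1.27 on both of its changed probe sets. It is known as a manganese and zinc transporter, so it does not do what the list's name says. The apical calcium channel Trpv6, at -0.57, and the vitamin D receptor Vdr, at -0.41, did not pass over all probe sets. Adjusted over the list alone, 6 members were lower and 1 higher, the last being Calb1 at 0.19 with a mean of 3.52 in the knockout, near the bottom of the scale. As a group the list was lower in the camera test with a preset correlation (adjusted p = 2.98e-05), with adjusted p = 0.115 with an estimated correlation. Its score was lower in every knockout sample than in any control sample (exact permutation p = 0.0286, the smallest possible), but without the 3 changed genes the scores of the other 9 members overlapped (exact permutation p = 0.114). Without knockout 2, S100g no longer passed (adjusted p = 0.0578).

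The transcript of the iron exporter was lower as well. Slc40a1 encodes ferroportin, which carries iron out of the enterocyte. It fell by 1.78 on its brighter probe set, from 12.30 ± 0.11 to 10.52 ± 0.35 (SD, n = 4 each; adjusted p = 0.00143 in limma), and by 1.94 on the dimmer one. It was the only member of the iron and haem handling list to pass; 16 of 17 did not. Adjusted over the list alone, 3 were lower, the others being the ferritin heavy chain Fth1 at -0.25 and the folate and haem transporter Slc46a1 at -0.95. The list was lower in camera (adjusted p = 0.00165), with adjusted p = 0.464 with an estimated correlation. Its scores overlapped between the groups (exact permutation p = 0.0857). Without Slc40a1 the scores of the other 16 members overlapped too (exact permutation p = 0.257).

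At the brush border, the alkaline phosphatase Akp3 fell 7.97-fold, from 12.79 ± 0.30 to 9.80 ± 0.55 (SD, n = 4 each; adjusted p = 0.00127 in limma). The related phosphatase Alpi had a value of -0.22 and did not pass (adjusted p = 0.599). The sequences of these paralogs are similar, so the probe sets may not fully separate them. Of 19 measured brush border hydrolases 1 fell and 18 did not pass, yet 15 had values above 0. Adjusted over the list alone, 5 were higher and 3 lower; among the higher ones were the peptidases Anpep at 0.43 and Cndp2 at 0.42. Cndp2 is known as a peptidase of the cytosol, so it does not do what the list's name says. The list was higher in camera (adjusted p = 0.0388), with adjusted p = 0.762 with an estimated correlation. Its median member value was 0.22, while its mean was -3.22e-04, opposite in sign to the test, and its scores did not separate the groups (exact permutation p = 0.971).

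No member of the microvillus, fat, sugar and amino acid lists passed, but most of their values lay above 0. In the microvillus structure list, 16 of 17 were above 0, with a median of 0.12; Eps8l3 had 0.25 and Krt20 had 0.22. The list passed in camera (adjusted p = 6.89e-06), with adjusted p = 0.285 with an estimated correlation, and its score was higher in every knockout sample than in any control sample (exact permutation p = 0.0286). In fat absorption and chylomicron assembly 22 of 24 were above 0 (median 0.16), including the sterol transporter Abcg5 at 0.34, while the lipoprotein receptor Scarb1 had -0.58. The camera p was 2.82e-05 after adjustment, with adjusted p = 0.671 with an estimated correlation, and the scores overlapped (exact permutation p = 0.257). In sugar transport and metabolism all 11 were above 0 (median 0.29), among them the gluconeogenic enzyme Pck1 at 0.87 and Txnip at 0.29. That list's camera test gave an adjusted p of 1.63e-05, with adjusted p = 0.464 with an estimated correlation, and the scores overlapped (exact permutation p = 0.0571). In amino acid and peptide transport 13 of 15 were above 0 (median 0.14), with Slc43a2 at 0.34 and Slc38a5 at -1.39. For these transporters camera gave an adjusted p of 0.00752, with adjusted p = 0.679 with an estimated correlation, and the scores overlapped (exact permutation p = 0.571). Adjusted over the list alone, 0 members passed in the microvillus, fat and sugar lists, and in the amino acid list 1 was higher and 1 lower.

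Among gut hormones, Gip was the only one to change. Gip encodes the incretin of the K cells in the upper gut. It fell by 2.64, from 11.41 ± 0.25 to 8.77 ± 0.30 (SD, n = 4 each; adjusted p = 2.01e-04 in limma). The remaining 21 of the 22 measured members of the enteroendocrine hormone and granule protein list did not pass, and adjusted over the list alone Gip was still the only one. The somatostatin gene Sst had -0.61 (adjusted p = 0.561). Pancreatic islet markers, 2 of which (Iapp and Gcg) are also in this list, were below 0 in 6 of 7 cases (median -0.30), and the islet score was 1.74 in control 4, whose hormone score was 0.57. Without control 4 the hormone list lost its camera call (adjusted p = 0.0652). The list was lower in camera (adjusted p = 5.37e-04), with adjusted p = 0.679 with an estimated correlation, and its scores were separated (exact permutation p = 0.0286). Without Gip the scores of the remaining 21 members overlapped (exact permutation p = 0.429).

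Markers of the stomach and of the Brunner glands, the mucous glands of the duodenum, held no changed gene. In the gastric list 22 of 26 values were below 0. Sult1c2 had -1.03 (adjusted p = 0.0862 in limma) and was the 1 member lower when adjusted over the list alone, and Muc1 had -0.65. The camera p was 0.00562 after adjustment, with adjusted p = 0.652 with an estimated correlation, and the scores overlapped (exact permutation p = 0.286). All 5 measured Brunner gland markers were below 0, including the growth factor Egf at -0.53 and the trefoil peptide Tff2 at -0.31. Egf read 4.09 in the knockout and 4.63 in the control, below the array medians. In the Brunner list 0 passed adjusted over the list alone. Muc6, Tff2, Muc5ac and Gkn3 were put in both lists, so the gastric and Brunner results are not independent of each other. Camera gave the Brunner list an adjusted p of 0.0388, with adjusted p = 0.464 with an estimated correlation, and its scores were separated (exact permutation p = 0.0286). In the colon marker list 9 of 12 were below 0 and 0 passed adjusted over the list alone (camera, adjusted p = 0.0486, and adjusted p = 0.464 with an estimated correlation). The colon scores overlapped (exact permutation p = 0.0857). Sycn of the colon list is also in the exocrine pancreas list.

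The remaining lower genes were an enzyme and a pair of transporters. Ugt2b38, of a family that conjugates small molecules with glucuronic acid, fell by 3.53, from 10.02 ± 0.60 to 6.50 ± 0.58 (SD, n = 4 each; adjusted p = 0.00226 in limma). It belongs to a family of similar sequences, so its probe set may also read relatives. With a trended and robust prior it did not pass (adjusted p = 0.0643). The sodium sulfate cotransporter Slc13a1 fell by 0.86 on its brighter probe set (adjusted p = 0.0106); its dimmer one had -1.21 and did not pass. The thiamine transporter Slc19a3 fell by 0.66 and 0.57 and was the only member of the retinoid and vitamin handling list to pass, with 16 of 17 not past. Adjusted over that list alone, 2 were lower and 1 was higher, the last being the retinol-binding protein Rbp2 at 0.28, and the list did not pass in camera (adjusted p = 0.608). Slc19a3 lost its call without control 1 (adjusted p = 0.0642), control 3 (0.0503), knockout 1 (0.0763), knockout 2 (0.0984) or knockout 3 (0.0531). Its probe set at -0.57 also lost its call without control 2 (0.133) or control 4 (0.138). With the pancreas covariate that probe set had -0.56 and lost its call too (0.0952). Slc13a1 lost it without knockout 1 (0.0623) or knockout 2 (0.0744). Without control 2 and knockout 3 together both Slc13a1 (0.0609) and Slc19a3 (0.0882) lost their calls.

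Mt1, a metallothionein that binds zinc and copper, rose by 1.48 on its brighter probe set, from 12.20 ± 0.090 to 13.68 ± 0.077 (SD, n = 4 each; adjusted p = 4.70e-05 in limma). Its dimmer probe set had 1.16 (adjusted p = 0.0627). Acta1, skeletal muscle actin, rose by 0.83, from 7.24 ± 0.12 to 8.07 ± 0.15 (adjusted p = 0.00990), and lost its call without knockout 2 (adjusted p = 0.0578) or without control 2 and knockout 3 together (0.0776). Its probes may also read other actins, and smooth muscle markers also had higher means in the knockout. Acta1 did not follow the smooth muscle score across the knockout samples, however. In knockouts 1 and 3 the score was 0.32 and 0.27, and Acta1 read 7.94 and 8.01. In knockouts 2 and 4 the score was -0.041 and -0.083, and Acta1 read 8.04 and 8.28. Since only Mt1 and Acta1 rose, 8 further genes with the smallest p were named by rule, and none of the 8 passed. Resf1 had values between 0.41 and 0.50 on 4 probe sets (lowest adjusted p = 0.0627), Mtmr11 0.76, Acot12 0.63 and Pof1b 0.56. Scamp1 had 0.54, Sgpl1 0.49, Bend7 0.46 and Ehd1 0.39.

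Smooth muscle, exocrine pancreas and enteric neuron and glia markers lay mostly on one side of 0, without a changed gene. The fibroblast, endothelial and adipocyte lists were more evenly split, with 9 of 15, 8 of 13 and 5 of 8 markers above 0, and did not pass in camera. The macrophage, T cell and MHC class II lists had 14 of 15, 14 of 16 and 9 of 9 above 0, and did not pass either. All 17 smooth muscle markers were above 0 in the knockout (median 0.21), with Synm at 0.40 and Actg2 at 0.52, and none passed singly or adjusted over the list alone (0). The camera p was 4.12e-08 after adjustment, with adjusted p = 0.570 with an estimated correlation, and the scores overlapped (exact permutation p = 0.0571). All 22 exocrine pancreas markers were below 0 (median -0.45). Their scores ranged from -1.21 in control 3 to 1.03 in control 4, and the groups overlapped (exact permutation p = 0.429). Of these, Klk1, at -0.92, was the 1 member lower when adjusted over the list alone, and Pnliprp2 had -1.01. The camera p was 6.11e-04 after adjustment, with adjusted p = 0.818 with an estimated correlation. In the enteric neuron and glia list 12 of 15 were below 0, with Chat at -0.26 and Gfap at -0.21, and 0 passed adjusted over the list alone (camera, adjusted p = 0.0388, and adjusted p = 0.658 with an estimated correlation). The neuron and glia scores overlapped (exact permutation p = 0.171).

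**Figure D2:**
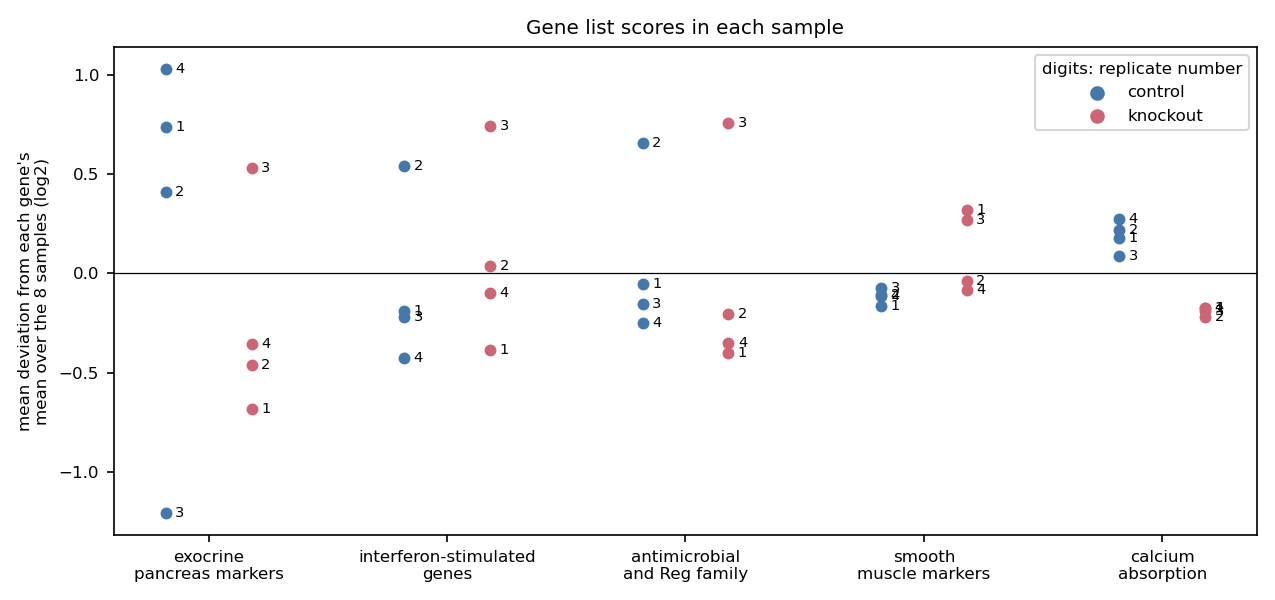
Scores of 5 gene lists in each sample, as the mean over members of the deviation from each gene's mean over the 8 samples (log2), with control points in blue, knockout points in red and the replicate number beside each point. The calcium absorption scores, which include the 3 changed genes, separate the groups, while the exocrine pancreas scores overlap and run from -1.21 in control 3 to 1.03 in control 4.

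**Figure D3:**
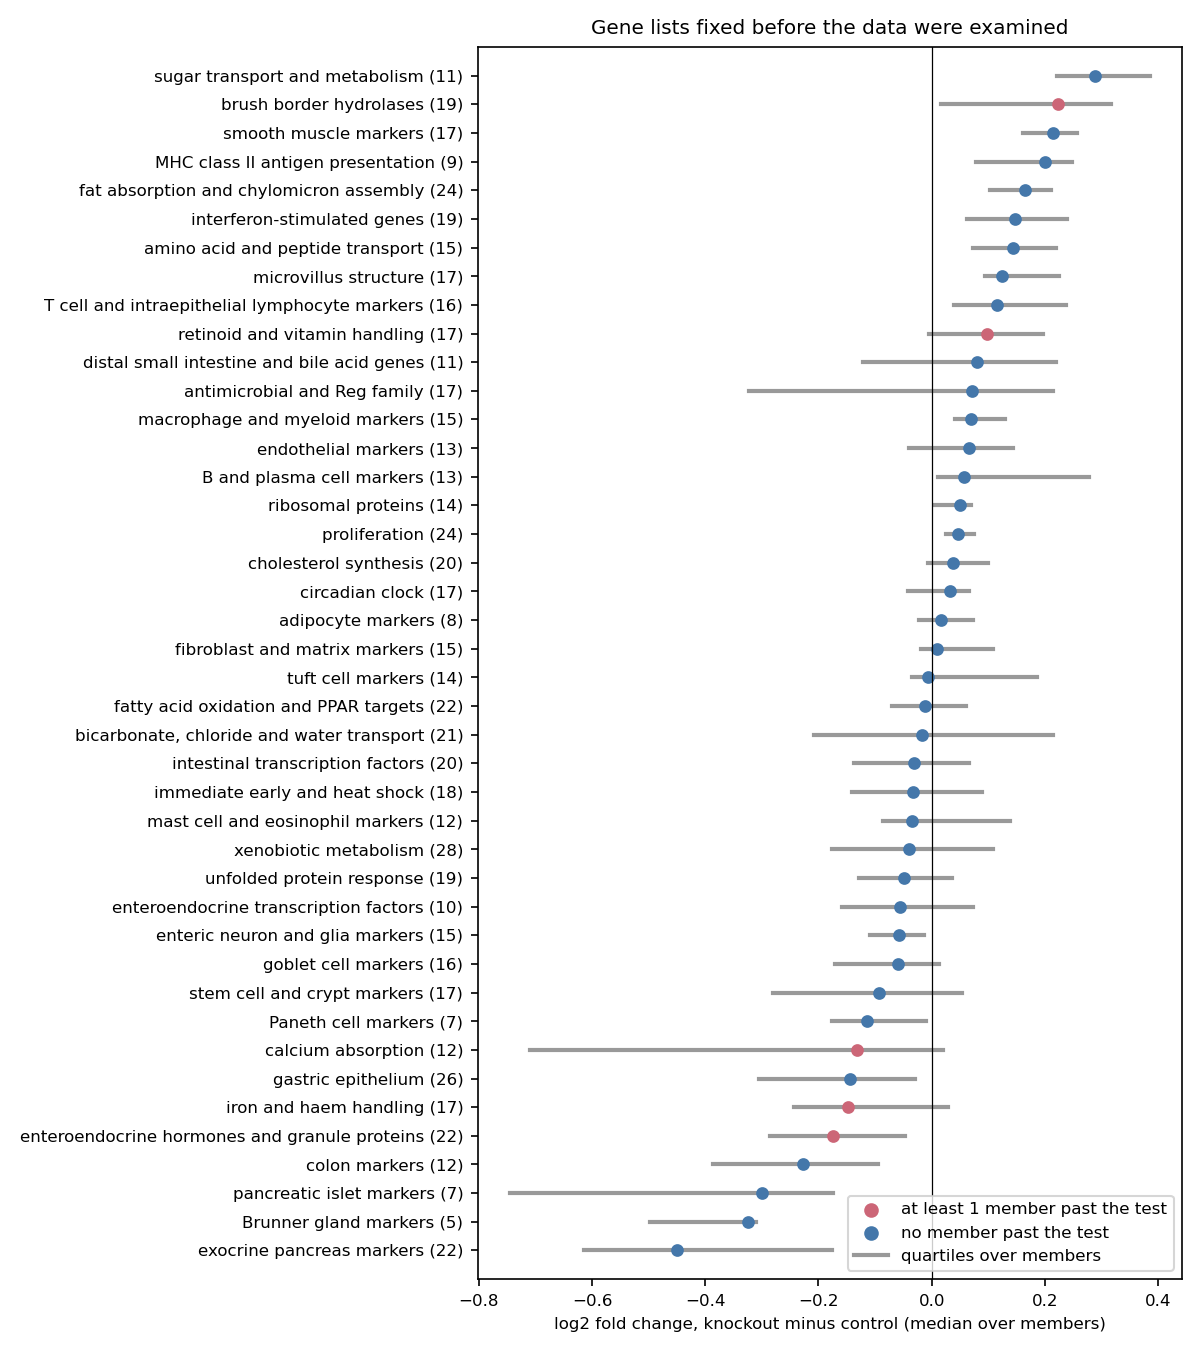
Median log2 change, knockout minus control, over the measured members of each of 42 gene lists (points), with the quartiles over members (lines) and the number measured in parentheses; red points mark lists with at least 1 changed member. The medians run from -0.45 for exocrine pancreas markers to 0.29 for sugar transport and metabolism.

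In total, 14 of 42 lists passed in camera with a preset correlation, 6 higher and 8 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. The list results describe direction only, while the changed genes rest on their own tests. The calcium, iron, microvillus, fat, sugar and smooth muscle lists passed in camera with each sample left out in turn, and the other 8 did not. Of those that kept their call, only the calcium and microvillus lists had scores that separated the groups. The brush border list lost its call without control 2 (adjusted p = 0.388), control 4 (0.0949), knockout 1 (0.0793), knockout 2 (0.0607) or knockout 4 (0.151). The colon list lost it without control 1 (0.193), control 4 (0.0949), knockout 1 (0.0628) or knockout 2 (0.0607). The Brunner list lost it without control 2 (0.136), control 4 (0.0652) or knockout 1 (0.145), and the neuron and glia list without control 4 (0.287), knockout 2 (0.0501) or knockout 3 (0.218). The enteroendocrine list lost it without control 4 (0.0652) or knockout 3 (0.0525), and the amino acid list without control 2 (0.155) or control 4 (0.0598). The gastric list lost it without control 2 (0.286) and the pancreas list without control 4 (0.141). With the exocrine pancreas score as a covariate the Brunner list (adjusted p = 0.118), the colon list (0.118), the brush border list (0.183), the amino acid list (0.111) and the neuron and glia list (0.111) lost their calls. Without control 2 and knockout 3 together the amino acid list (0.0786) and the neuron and glia list (0.144) lost theirs. Under repeated quantile normalization the brush border (0.0748), colon (0.0750) and neuron and glia (0.0525) lists lost theirs, as did the brush border list with median centring (0.0508). Among probe sets above the median mean the Brunner (0.108) and colon (0.386) lists lost theirs, as did the colon list with the mean of a gene's probe sets (0.0823). Lists of goblet, Paneth, tuft and stem cells, of proliferation and of immune cells did not pass in camera with either correlation. Values were below 0 for 11 of 16 goblet markers (median -0.06), 5 of 7 Paneth markers (median -0.11) and 11 of 17 stem cell markers (median -0.09). Among their members, Klk1 of the goblet list had -0.92 and Defa3 of the Paneth list 0.20. Ascl2 of the stem cell list had -0.39, -0.30 and -0.10 on its probe sets. None of these genes passed over all probe sets. Defa3 read 4.33 in the knockout and 4.13 in the control, below the array medians. Adjusted over the list alone, Klk1 was the 1 lower member of the goblet list, and 0 passed in the Paneth and stem cell lists. Klk1 is also in the exocrine pancreas list, so its value there and here is the same result.

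Measures of RNA quality overlapped between the groups. The Actb signal at the 3′ end minus that at the 5′ end was 0.39 ± 0.061 in the knockout and 0.50 ± 0.076 in the control (SD, n = 4 each; exact permutation p = 0.0857). The 18S ribosomal probes read 8.66 ± 1.64 and 8.22 ± 0.83 (exact permutation p = 0.743).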

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

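The tests of the hybridization control mix and of metal were chosen only after the result was seen; the counts of splits, the brightness test and both pancreas tests were set before their values were known. In 174 sets of 4 samples, 13 held a sample far from the other 3, 7 in the knockout and 6 in the control; chance gives about 1 in 20.

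Among named genes, a probe set of Ehd1 read 9.93 in control 4, below the other controls, which lay between 10.08 and 10.09. Mt1 read 13.80 in knockout 2, above 13.64 to 13.66 in the others. In control 4 the enteroendocrine hormone score was 0.57 and the stem cell score 0.20, both high. In control 2 the retinoid and vitamin score was -0.42 and the circadian clock score -0.14, both low, and in control 1 the ribosomal protein score was -0.12, also low. In knockout 2 the pancreatic islet score was 0.54 and the B and plasma cell score 0.39, both high within its group, although control 4 had the highest islet score of all 8 samples, 1.74. In knockout 2 the Gapdh 3′ minus 5′ value was -0.056, above the others. In knockout 3 the antimicrobial and Reg score was 0.76, high, while the sugar score was 0.012 and the bicarbonate, chloride and water score -0.18, both low.

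Array probes for Cre, a gene that is both in the hybridization control mix and in the knockout's transgene, read higher in the knockout. Set against bioB, bioC and bioD of the same mix they were 4.78 ± 0.060 in the knockout and 4.53 ± 0.079 in the control (SD, n = 4 each), a difference of 0.244 (exact permutation p = 0.0286, the smallest possible). A larger amount of mix on the knockout arrays would raise all its genes alike and leave that difference near 0, which was not seen. That difference is also the value that flagged the result, so it is no separate test. The bioB, bioC and bioD probes themselves read 8.48 ± 0.11 in the knockout and 8.51 ± 0.19 in the control (exact permutation p = 0.800). A shift of the bright end of the scale would move other bright probe sets, but 297 probe sets as bright as the Cre probes moved by 0.0076 relative to those as bright as the bio probes. Set against bioD alone, each of the 4 Cre probe sets separated the groups, with differences of 0.18 to 0.26. They read the same gene, so they are not independent of each other. Transcripts of the Cre transgene may add to the signal; this separation raised the idea and so does not test it, and it stays open.

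Mt1 rose while Mt2 had a value of -0.44 and did not pass the test. Zinc or another metal would be expected to raise Mt2 and the zinc exporter Slc30a1 too, but the highest upper 95% limit of their changes was 0.491, below the lowest lower limit of the Mt1 changes, 0.79. That Mt2 did not rise was part of the result that raised the question, so its limit is no separate test. The Slc30a1 limit, 0.491, argues against a metal response that raises Slc30a1 as much as Mt1, while a smaller one stays open. A sequence of Mt1 in the transgene may also raise its probes; the transgene's sequence is not given in the sources used here, and this was not tested. An effect of Pdx1 loss on Mt1 itself stays open too, untested.

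Pdx1 is also made in the pancreas, whose markers had lower values in the knockout. The 22 measured markers included abundant ones such as Ctrb1, at 13.96 in the knockout and 14.01 in the control, and Cela3b, at 13.93 and 14.10; 2 of the 22 are also in another list, and all 22 lay above the median probe set in every sample. With their score as a covariate Pdx1 still changed by -2.47 (adjusted p = 0.00180 in limma), so less exocrine pancreas does not account for the whole of its fall. The score holds exocrine markers only, so this fit does not test islet tissue. Control 3 had the lowest exocrine and islet scores of all samples, -1.21 and -0.73. Its brighter Pdx1 probe set read 8.16, above every knockout sample. Knockout 2, with an islet score of 0.54, read 5.91. The score ranged over 2.23 within the control group, wider than the difference of -0.48 between the groups (exact permutation p = 0.429), which is consistent with varying amounts of attached pancreas between mice. Removal of Pdx1 from the epithelium, which the labels name, remains as the explanation of the lower Pdx1, as a hypothesis on these data.

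Among the 35 splits of the 8 samples into 4 and 4, only 1, the real one, gave 19 or more changed probe sets. The highest of the others gave 6. A share of 1 in 35 is the smallest these splits can give. The other splits mix the groups, which raises their spread where genes truly differ. Chance is thus less likely for this number but is not excluded. Nor can it be excluded for the gene lists with a preset correlation: 21 of the 35 splits gave 14 or more lists, and the highest of the others gave 22.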

How the results depend on the processing

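The fits without control 2 and knockout 3 and with the pancreas covariate were chosen after seeing the data. Signal over background limits the dim probe sets, for which no detection calls were used. The number of changed probe sets stayed within 1.5 times the 19 reported under repeated quantile normalization, median centring, both filters, the trended prior (where Ugt2b38 lost its call), array weights and the added fold minimum. In an ordinary linear model, where the variance is not pooled over probe sets, 2 passed, 1 higher and 1 lower. Pdx1 kept its changes of -2.59 and -1.85, with adjusted p of 0.113 and 0.153 in that model. With values under 5 set to 5, 4 passed, 2 of them lower, and Pdx1 had -2.59 (adjusted p = 0.0833) and -1.82 (adjusted p = 0.103). At that floor 42.7% of probe sets had no variance left. Gip and Akp3 had no value under 5 and kept changes of -2.64 and -3.00, yet lost their calls (adjusted p = 0.0508 and 0.130 in limma). Their loss thus came through the variance pooled over probe sets or the adjustment, not through their own values. Which of these it was, was not tested. At an adjusted p under 0.10 there were 29, 7 of them higher. At an unadjusted p under 0.05 with a fold of at least 1.5 there were 130, 45 higher and 85 lower. The count of higher probe sets was 4 among those above the median mean, 5 among those with a mean above 6 and 5 with array weights; the filters tested fewer probe sets, and for the weights the cause was not tested. With an estimated correlation 0 lists passed.

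Leaving out each sample in turn gave 13 to 20 changed probe sets, 1 to 3 higher and 12 to 18 lower, Pdx1 changes of -2.71 to -2.44 and -1.99 to -1.73, and 10 to 18 lists. The lowest counts of changed and of higher probe sets, 13 and 1, came without knockout 2. Without control 2 and knockout 3 there were 17 changed probe sets, 14 of them among the 19, and Acta1 (adjusted p = 0.0776), Slc13a1 (0.0609) and Slc19a3 (0.0882) lost their calls; 14 lists passed, 12 of them shared. With the pancreas covariate there were 21 changed probe sets, 17 of them shared, and 11 lists, 8 shared; the Brunner, colon, brush border, amino acid and neuron and glia lists lost their calls. Among single named probe sets other than those of Pdx1, 62 results lost their call and 14 gained it. The other 677 were unchanged, which includes results that passed neither before nor after. For the Pdx1 probe sets 4 results lost their call and 33 kept it. Among lists 49 lost their call and 51 gained it. The other 571 list results were unchanged, again counting lists that passed neither before nor after. No result with a test reversed. A single Pdx1 probe set could not be given with a mean above 6, since the filter removes it, nor a dim Acot12 probe set with the floor at 5, nor the pancreas list under its own covariate.

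The replicate numbers were not found to pair the samples. Deviations of same-numbered samples correlated at 0.0083, -0.085, -0.20 and 0.23 across probe sets with a mean above 6, 1 of 4 over 0.1, and 1 of 8 samples correlated best with its own number. Knockouts 1, 2, 3 and 4 correlated best with controls 3 (0.40), 4 (0.23), 2 (0.72) and 1 (0.46). The labels tie no number to a litter, so litters could not be modelled, and pairing under other numbers stays open. With the replicate number as a block, 24 probe sets changed, 16 of them among the 19, Pdx1 had adjusted p of 0.00460 and 0.00447, 19 lists passed, and Acta1 (adjusted p = 0.0845) and Slc19a3 (0.0971) lost their calls.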

Other observations

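The genes and samples here were chosen after their values were seen. Control 2 and knockout 3 stood apart from the other 6 samples in some immune and defence lists. Their interferon-stimulated gene scores were 0.54 and 0.74, their antimicrobial and Reg scores 0.66 and 0.76, their MHC class II scores 0.39 and 0.74, and their T cell scores 0.30 and 0.73, while their xenobiotic metabolism scores were -0.51 and -0.88. The lists of B and plasma cells, macrophages, and mast cells and eosinophils did not set them apart: their B and plasma cell scores were -0.13 and -0.071, their macrophage scores 0.048 and 0.0032, and their mast cell and eosinophil scores 0.013 and -0.016. They lay at one end of the leading principal component, which held 39.5% of the variance. The deviations of this pair from their group means correlated at 0.72 across probe sets with a mean above 6, the highest of the 16 pairings of a knockout with a control sample.

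Some single genes that missed the test had large values. Ncoa4, which delivers ferritin to lysosomes, had -1.07 and -0.99 on its probe sets (adjusted p = 0.157 and 0.219 in limma), and both separated the groups. The glutathione transferase Gsta4 had -1.07 (adjusted p = 0.0983). The xenobiotic metabolism list, which holds Gsta4, had 11 values above 0 and 17 below, and did not pass in camera (adjusted p = 0.954). The monocarboxylate transporter Slc5a12 had 1.56 and 1.53 (adjusted p = 0.294 and 0.421), in the list of distal small intestine genes, which did not pass as a list. Vnn1, a pantetheinase of enterocytes, had 0.59 and 0.53.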
